A study of Mus musculus with 2 samples.

How the data were processed

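H3K4me2 ChIP-seq peak lists from midbrain of mouse embryos at embryonic day 14.5 were analysed. Per the labels, replicate 1 came from 24 embryos and replicate 2 from 34, of mixed sex, and libraries were size selected at 300 to 500 bp. The labels call them biological replicates, and both form 1 group, so that no groups were compared. A control library was not used here.

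Per the file headers, reads were aligned to mm10 and peaks were called by the authors for each library separately and on both libraries pooled. A replicated list was then derived from the pooled list and the 2 library lists. Per the file headers, the list of replicate 1 was derived from its alignment and 2 further input files, and that of replicate 2 from its alignment and 1 further input file, whose content is not stated. Aligner, peak caller, peak threshold and the rule for the replicated list are not given in the sources used here. The lists give for each peak a position, a summit and 4 values. The fold enrichment of each peak, a linear ratio, is the authors' own deposited value. A −log10 p and a −log10 q value per peak were deposited by the authors as well. The deposited score column was not used. All 36312 replicated peaks on assembled chromosomes had the bounds of a pooled peak. Lists held weak peaks, down to a −log10 p of 2.01 in replicate 1 and 2.04 in replicate 2, and 33.4% and 29.4% of peaks had a −log10 q below 5.

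Gene positions came from GENCODE release M21 on GRCm38, which has the coordinates of mm10, and no peak reached past the end of its chromosome there. In all 21911 protein-coding genes on 21 chromosomes were used, 1 per symbol. For the 27 symbols annotated more than once, the longest gene was kept. Peaks on scaffolds outside these chromosomes, 16 in each library, were left out of the comparisons. Coordinates are counted from 1. A promoter was marked where a peak lay within 1 kb of the gene's annotated 5' end in both libraries. Breadth was the number of bp covered by peaks within 10 kb either side of the 5' end. Peaks within 1 kb of each other were joined into regions, and regions more than 2.5 kb from the annotated 5' end of every gene were distal. Only the most upstream 5' end of each gene was used, so distal regions can include promoters of other transcripts. Distal regions were counted within 100 kb of a gene's 5' end. Regions were classed by position as promoter (within 1 kb of a 5' end of any gene), exon, intron or intergenic, in that order. CpG content was the observed over expected ratio in 1 kb centred on the 5' end, and the classes were terciles.

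Gene lists were compared with 10000 random lists of the same size, matched on decile of promoter CpG content. A list stood apart where its median lay in the highest 2.5% or the lowest 2.5% of random lists in both libraries. These percentiles describe the 2 libraries and are not p-values, since genes are not replicates. The lists comprised 26 of 384 different genes, 3 of them in more than 1 list, and 3 gene families as negative controls. Tested on simulated data over 21911 genes, lists of 15 members with no change were called wide in 2.5% and narrow in 2.25% of 400 simulations. Lists of 10 members with breadth raised by a factor of 2 were called in 85% of 20 simulated lists and those of 20 members in 95% of 20, while a factor of 1.5 gave 40% and 70%, again of 20 each. These simulations used breadth in replicate 1 alone, so their rates are not those of the rule that requires both libraries. Overlap between libraries was set beside 100 random placements of the replicate 1 peaks, merged only where they overlapped. Depth is unknown from peak lists, so no intervals were given.

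Gene lists, comparisons, the alternatives below except the last, and the rule for named genes were fixed before the data were examined. Named were the 25 genes with the largest mean breadth (5' ends within 10 kb named together), the 2 widest and 2 narrowest members of each list, the 10 widest replicated regions, the 10 replicated peaks with the highest fold enrichment (1 per region) and the 5 genes that differed most between libraries. Other members of lists, among them Pax3, Otx1, En1, Fgf8, Slc32a1, Slc17a6, Pax2 and Hes5, are examples, some of them chosen after their values were seen. Genes of other types at the widest regions were looked up after the regions were known.

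Alternatives were a −log10 q of at least 2 or 5, equal numbers of peaks per library, each library alone, overlap of 50% of the peak or of both peaks, a breadth window of 5 kb, other matching of random lists, the authors' pooled and replicated lists, a promoter window of 2 kb or any transcript 5' end, a distal window of 50 kb or distance of 5 kb, and joining at overlap or within 3 kb. After several listed genes were seen to lack a peak at the most upstream 5' end, the 5' end of the APPRIS principal transcript was added. Analyses used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and matplotlib 3.10.9 for figures.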

Results

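Dimethylated lysine 4 of histone H3 (H3K4me2), a mark of promoters and enhancers, was mapped by ChIP-seq in midbrain from mouse embryos at embryonic day 14.5. The only group held 2 libraries, replicate 1 from a pool of 24 embryos and replicate 2 from a pool of 34, of both sexes. Each library came with its own list of peaks, and a pooled list and a replicated list covered both libraries. Peak lists carry no read counts, so the sequencing depth behind each value is unknown. With 1 group, no p-value between conditions was possible. Values after ± are SDs over the 2 libraries (n = 2), which describe the spread between the 2 pools. Positions are on mm10 (GRCm38).

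How much of the genome carried H3K4me2, and how alike the 2 pools were, was asked first. Replicate 1 had 45996 peaks and replicate 2 had 43366, a mean of 44681 ± 1860 (SD, n = 2). On the assembled chromosomes these covered 54.6 Mb and 51.9 Mb, or 2.00% and 1.90% of chromosome length. Gene-rich chromosome 11 held 27.1 ± 0.602 peaks per Mb and chromosome 19 held 23.0 ± 1.01, against 7.18 ± 0.141 on the X chromosome and 0.0926 ± 0.00771 on the Y chromosome. Median peak width was 699 bp in replicate 1 and 743 bp in replicate 2. The authors' fold enrichment per peak had a median of 6.30 and 7.87. The replicated list held 36326 peaks with a median width of 1075 bp.

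Of the replicate 1 peaks on assembled chromosomes, 79.6% overlapped a replicate 2 peak by at least 1 bp, and 87.1% of replicate 2 peaks overlapped a replicate 1 peak. The covered sequence common to both libraries made up 81.0% of the sequence covered in either. Random placement of the replicate 1 peaks on the same chromosomes gave an overlap of 3.65% of peaks on average over 100 placements, with a highest value of 3.83%. Peaks without a partner were weak and narrow. In replicate 1 their median fold enrichment was 3.15 and their median width 246 bp, against 11.6 and 993 bp for shared peaks. They held 4.82% of the covered sequence in replicate 1 and 2.81% in replicate 2. With peaks ordered by fold enrichment and split into 4 equal groups, 41.4% (replicate 1) and 59.2% (replicate 2) of the weakest group were shared, and 100% of the strongest group in both libraries. Requiring each peak to be overlapped over 50% of its length gave 72.5% and 81.7%.

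**Figure D1:**
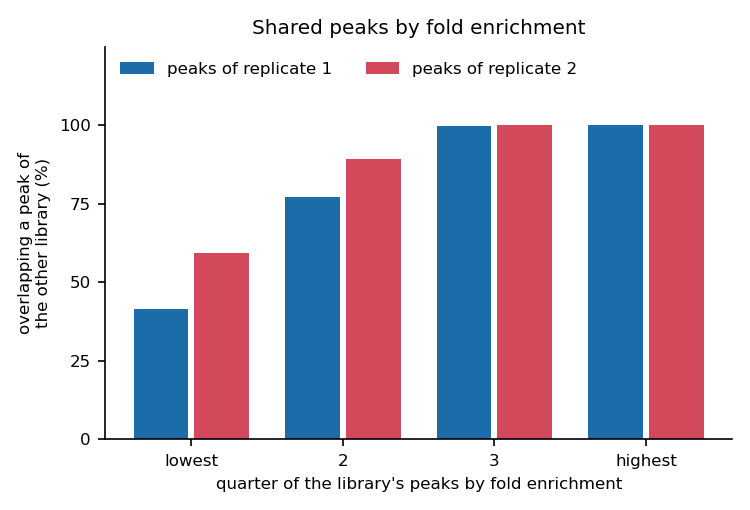
Share of each library's peaks (%, vertical axis) that overlapped a peak of the other library by at least 1 bp, for 4 equal groups of the library's peaks ordered by the authors' fold enrichment (horizontal axis). Shares are 41.4% and 59.2% in the weakest group and 100% in the strongest.

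H3K4me2 lay at promoters more than at any other class of sequence. Peaks of the replicated list that lay within 1 kb of each other were joined into 29823 regions, of which 47.2% were promoter regions, 12.1% exonic, 18.5% intronic and 22.3% intergenic. A region took the first of these classes, in the order given, that any part of it overlapped. Promoter sequence, within 1 kb of an annotated 5' end of any gene, made up 3.75% of the genome and 41.0% of the covered sequence, a ratio of 10.9. Introns held 37.0% of the covered sequence, not far below promoters, exons 8.81% and intergenic sequence 13.2%. Exons were covered at a ratio of 2.37, introns at 0.953 and intergenic sequence at 0.245. In the separate libraries, promoters held 41.4% ± 1.07 of the covered sequence and intergenic sequence held 12.8% ± 0.289. Regions more than 2.5 kb from the most upstream annotated 5' end of every gene, called distal, numbered 17599 in replicate 1 and 15786 in replicate 2. Other transcript 5' ends were not excluded, so these counts can include alternative promoters.

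**Figure D2:**
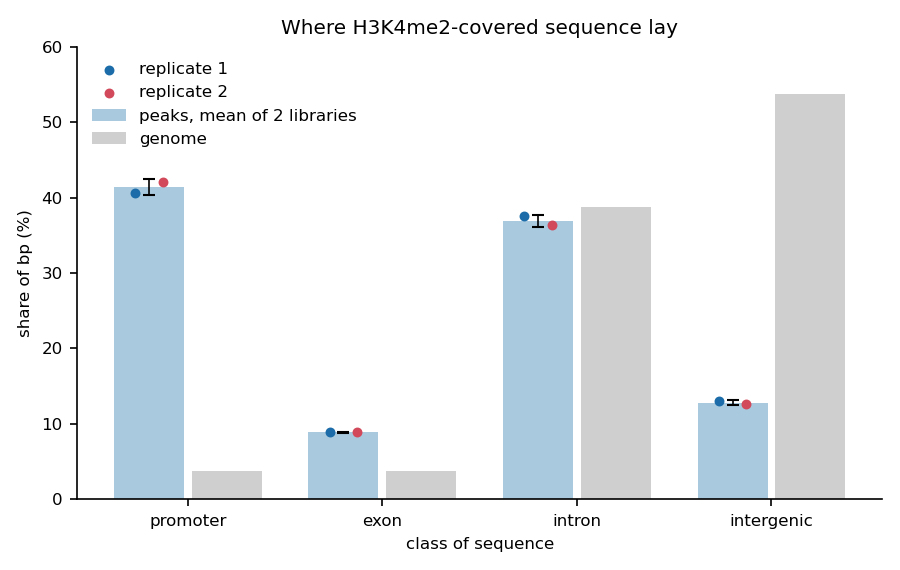
Share of H3K4me2-covered sequence and of the genome (% of bp, vertical axis) in promoter, exon, intron and intergenic sequence (horizontal axis). Blue bars are means of the 2 libraries with SD as error bars, points are single libraries and grey bars are the genome; promoters hold 41.4% of covered bp and 3.75% of the genome.

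Promoters of most protein-coding genes were marked, and the share was highest in the CpG-rich class. A gene was called marked where a peak lay within 1 kb of its annotated 5' end in both libraries, which held for 13775 of 21911 protein-coding genes (62.9%). Among genes in the CpG-poor class of promoters 8.27% were marked, in the middle class 81.1% and in the CpG-rich class 99.2%. Only 223 genes were marked in a single library. Breadth, the sequence covered by peaks within 10 kb either side of the 5' end, had a median of 2.85 kb ± 0.0799 over marked genes. Across the 21911 genes, breadth in the 2 libraries had a Pearson r of 0.993 and a Spearman rho of 0.992, which describes genes within these libraries, since genes are not independent replicates. Replicate 1 had the larger breadth at 64.1% of the marked genes. Breadth reached 10 kb in both libraries at 196 of the 21911 genes, marked or not, and 6254 genes had no peak in the window in either.

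Genes that pattern the midbrain and the isthmus, which encode transcription factors and secreted signals, carried the widest H3K4me2 of 29 gene lists. All 15 members were marked, with a median breadth of 13.0 kb ± 0.407 (SD, n = 2), against 2.69 kb for random lists of the same size and promoter CpG content. Meis2, a TALE homeobox gene (chromosome 2, 115863064 to 116065839), was covered over the whole window at 20.0 kb. En2, an engrailed gene of the midbrain and cerebellum (chromosome 5, 28165694 to 28172166), had 17.5 kb ± 0.504. Pax3 had 16.9 kb ± 0.126, Otx1 16.2 kb ± 0.168 and En1 16.1 kb ± 0.209. Narrowest in this list were Pax8 at 2.57 kb ± 0.202 and Fgf17, which encodes a fibroblast growth factor of the isthmus, at 2.19 kb ± 0.0537. Fgf8, the signal of the isthmic organiser, had 4.21 kb ± 0.377. For this and all other lists the median is over members' means of both libraries and the SD is between the library medians.

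The GABAergic and glutamatergic lineage lists were also wide. In the GABAergic list 13 of 14 members were marked and median breadth was 10.7 kb ± 0.0764, against 2.65 kb for random lists. The LIM homeobox genes Lhx1 and Lhx5 were widest, at 19.0 kb ± 0.0502 and 18.2 kb ± 0.215, and Slc32a1, the vesicular GABA transporter, had 14.3 kb ± 0.0368. Zfpm1 and Helt were narrowest, at 4.67 kb ± 0.224 and 3.82 kb ± 0.153. All 14 members of the glutamatergic list were marked, with a median of 11.97 kb ± 0.0643 against 2.71 kb. Ebf3 had 18.9 kb ± 0.134, Barhl2 17.4 kb ± 0.587 and Slc17a6, a vesicular glutamate transporter, 13.7 kb ± 0.0184. Neurog1, a proneural factor, had 4.88 kb ± 0.558, and Neurod4 had 0.603 kb ± 0.0742.

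In the dopaminergic list 11 of 14 members were marked and the median was 3.55 kb ± 0.231, against 2.30 kb for random lists. Its percentile among 10000 random lists was 94.95 in replicate 1 and 98.7 in replicate 2, so the list did not stand apart in both libraries. Its widest members were Lmx1b at 13.1 kb ± 0.850 and Foxa1, a forkhead factor of the floor plate, at 7.87 kb ± 1.09. Th, the rate-limiting enzyme of catecholamine synthesis, and Aldh1a1, an aldehyde dehydrogenase of some dopaminergic neurons, were listed at 0 in both libraries. At Th another annotated transcript 5' end was marked in both libraries, and at the principal transcript's 5' end breadth was 0.363 kb ± 0.0792. Across the alternatives its percentile ran from 45.8, with peaks of a −log10 q of at least 5, to 99.2, with unmatched random lists, and the authors' pooled and replicated lists gave 98.6 and 99.0.

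Progenitor and general neuronal genes stood apart as well. Neural progenitor genes had a median of 7.79 kb ± 0.0643 (library medians 7.72 kb and 7.63 kb) with 14 of 15 marked, led by the SOXB1 genes Sox2 at 17.7 kb ± 0.383 and Sox1 at 15.2 kb ± 0.227, while Prom1 had 2.76 kb ± 0.0587. Notch1 was listed at 0 at its most upstream 5' end, and at the 5' end of its principal transcript it had 8.19 kb ± 1.07. Pan-neuronal genes had a median of 5.68 kb ± 0.351 with 14 of 15 marked. Tubb3, a neuronal tubulin, had 8.77 kb ± 0.253 and Mapt, which encodes tau, 7.51 kb ± 0.0622, whereas Map2 had 4.29 kb ± 0.101 and Elavl4 1.99 kb ± 0.168. At their principal 5' ends Map2 had 6.53 kb ± 0.279 and Elavl4 11.3 kb ± 0.122. Axon guidance genes, of which 22 of 23 were marked, had a median of 6.43 kb ± 0.397. Among them Efna5, an ephrin of the tectal map, had 13.7 kb ± 0.0898 and the ephrin receptor gene Epha4 had 11.7 kb ± 0.0870. Sema3a had 0.666 kb ± 0.0219 and Robo1 was listed at 0 at the most upstream 5' end. At the principal 5' ends Sema3a had 2.60 kb ± 0.165 and Robo1 7.59 kb ± 0.317.

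Mature synapse genes were marked at 14 of 15 promoters with a median of 4.38 kb ± 0.125 (library medians 4.33 kb and 4.15 kb), against 1.81 kb for random lists. Dlg4, which encodes the scaffold PSD-95, had 9.42 kb ± 0.156 and the NMDA receptor gene Grin2b 8.001 kb ± 0.183. Scn1a had 1.755 kb in replicate 1 and 1.644 kb in replicate 2, and Cacna1a was listed at 0. At their principal 5' ends Scn1a was listed at 0 and Cacna1a had 4.29 kb ± 0.0552. Chromatin regulators had a median of 4.05 kb ± 0.188 with 19 of 22 marked. Setd1b, a histone H3 lysine 4 methyltransferase, had 17.3 kb ± 0.0318 and Kdm6b, a histone H3 lysine 27 demethylase, 13.7 kb ± 0.110. Ezh1 had 1.71 kb ± 0.122, and Tet1 was listed at 0 although another of its transcript 5' ends was marked in both libraries. Housekeeping genes had a median of 4.30 kb ± 0.0141 (library medians 4.335 kb and 4.315 kb) with 22 of 23 marked, from Chmp2a at 9.55 kb ± 0.0750 and Eef2 at 9.54 kb ± 0.359 to Hprt at 1.87 kb ± 0.00141 and Gusb at 1.46 kb ± 0.0622. Each of the 9 wide lists was in the highest 2.5% of the random lists in both libraries. If every list could fall at either end, chance would place about 1.45 of 29 lists in the highest or lowest 2.5% in a single library. Some lists could not be called low, and the 9 calls required both libraries, so 1.45 is not the number to set beside them.

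**Figure D3:**
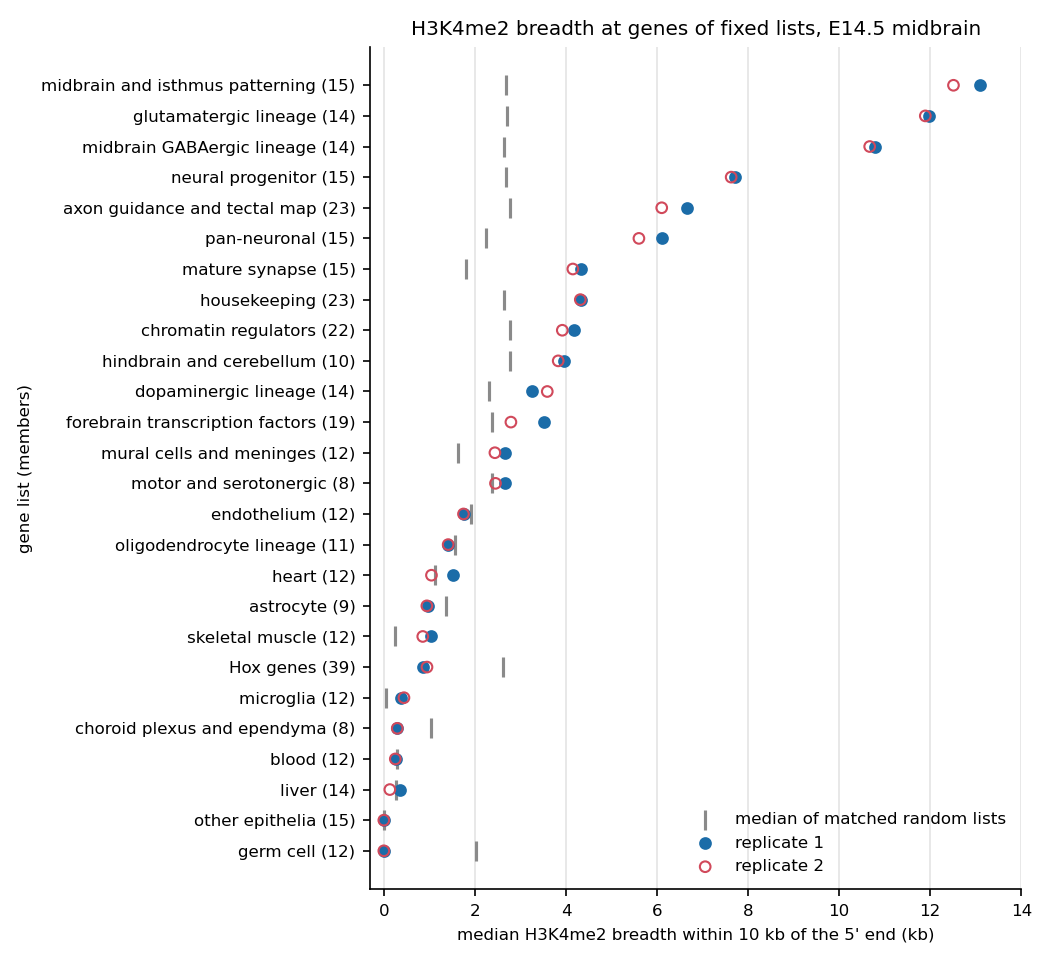
Median H3K4me2 breadth within 10 kb of the 5' end (kb, horizontal axis) for 26 gene lists (vertical axis, members in brackets). Filled and open points are replicates 1 and 2 and grey ticks the medians of CpG-matched random lists; midbrain and isthmus patterning lies at 13.0 kb against 2.69 kb, and Hox genes at 0.884 kb against 2.61 kb.

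Genes of other brain regions, and motor and serotonergic genes, gave mixed values. Forebrain transcription factors were marked at 16 of 19 promoters, with a median of 2.88 kb ± 0.521 that was not apart from random lists in both libraries. Emx2 had 15.5 kb ± 0.501 and Six3 13.5 kb ± 0.709, whereas Six6 had 1.63 kb ± 0.0177 and Fezf2, marked only at another transcript 5' end, 0.833 kb ± 0.573. The percentile of this list was 98.4 in replicate 1 and 84.6 in replicate 2, and across the alternatives it ran from 39.2, with peaks of a −log10 q of at least 5, to 99.3, with the authors' pooled list. The hindbrain and cerebellum list had a median of 3.88 kb ± 0.0940, against 2.76 kb for random lists, at percentiles of 94.3 and 94.8 in replicates 1 and 2, and was not apart. Matched on gene length its percentile was 99.3 and unmatched 99.0, which placed it in the highest 2.5%. Its members ran from Zic4 and Zic1 at 19.1 kb ± 0.197 and 17.5 kb ± 0.453 down to Hoxa2, marked in replicate 1 alone, at 1.87 kb ± 0.482 and Hoxb1, listed at 0. Motor and serotonergic genes had 2.56 kb ± 0.153, against 2.38 kb for random lists, and were not apart. Fev, a factor of serotonergic neurons, had 4.16 kb ± 0.344, Chat 2.75 kb ± 0.307, Phox2b, with no promoter peak, 0.627 kb ± 0.00636 and Tph2 0.358 kb ± 0.0127.

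Hox genes, which pattern the axis behind the midbrain, carried narrow H3K4me2. Of 39 genes 16 were marked, and median breadth was 0.884 kb ± 0.0615 against 2.61 kb for CpG-matched random lists, at percentile 0 of them in both libraries. Hoxd8 and Hoxd13 were widest, at 2.52 kb ± 0.110 and 2.47 kb ± 0.108, and Hoxa10 and Hoxa11 were listed at 0. Neighbouring Hox genes share sequence within their windows, so the 39 values are not independent. Random lists matched on gene length in place of CpG content put the Hox list at a percentile of 29.2, which ended the call.

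**Figure D4:**
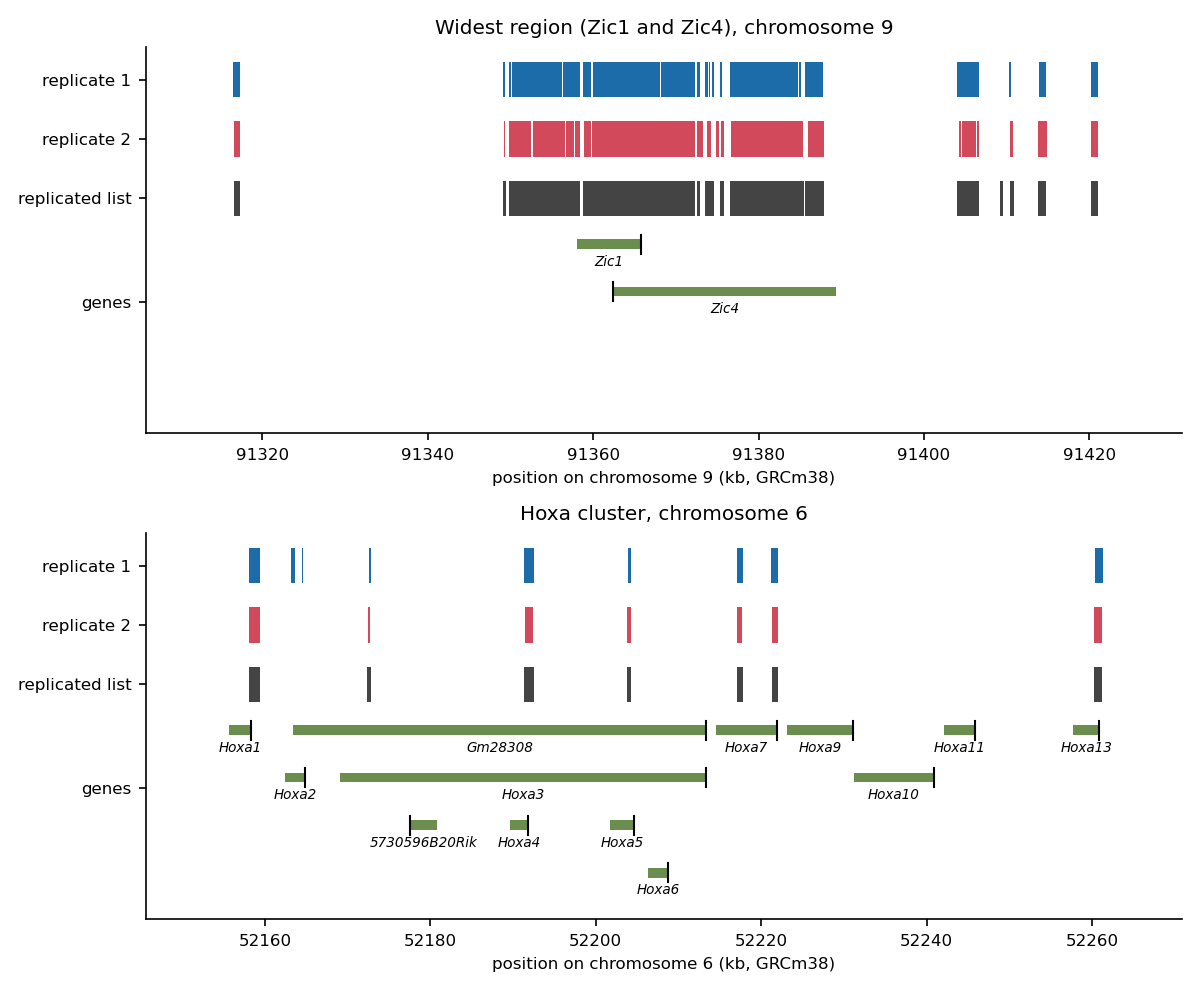
Peaks (blocks) of replicate 1, replicate 2 and the replicated list, with protein-coding genes (green, 5' end as a black tick), over windows of 125.3 kb on chromosomes 9 and 6 (position in kb, GRCm38). Peaks joined into a region of 38.8 kb at Zic1 and Zic4, while at the Hoxa genes, of which 5 of 11 were marked, median breadth was 1.097 kb.

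Genes of germ cells had a median breadth of 0 kb against 2.02 kb for random lists, the other list that stood low, with 2 of 12 marked. Gdf9 had 2.39 kb ± 0.144 and Ddx4, with no promoter peak, 2.006 kb and 1.901 kb in replicates 1 and 2, while the piRNA factor Mael and the protamine gene Prm1 were listed at 0. Lists of other organs were not called. The CpG-matched random median was 1.12 kb for heart, and the values of 0.260 kb for liver, 0.248 kb for skeletal muscle and 0 kb for other epithelia left little or no room for a low call. Unmatched, other epithelia fell in the lowest 2.5%, at percentile 1.82. Liver genes were marked at 3 of 14 promoters with a median of 0.245 kb ± 0.159. Apoh had 3.68 kb ± 0.107, but was listed at 0 at its principal 5' end, and Fgb, with no promoter peak, had 1.58 kb ± 0.0191. Albumin (Alb) and alpha-fetoprotein (Afp) were listed at 0, the latter with another transcript 5' end marked in both libraries. Skeletal muscle genes had 0.943 kb ± 0.124 and 4 of 12 marked, with Acta1 at 2.76 kb ± 0.120 but no promoter peak, Ckm at 1.94 kb ± 0.450 and the myosin genes Myh1 and Myh8 at 0. Heart genes had 1.28 kb ± 0.332 and 4 of 12 marked, from Ryr2 at 3.60 kb ± 0.107 and Tnni3, marked only at another transcript 5' end, at 3.21 kb ± 0.324 to Gata4 and Myh6 at 0, where Gata4 had another marked transcript 5' end and 0.562 kb ± 0.193 at its principal 5' end. In other epithelia 2 of 15 genes were marked and the median was 0 kb, and the widest windows were those of Sftpc at 4.84 kb ± 0.610 and Krt1 at 3.01 kb ± 0.426, both marked at another transcript 5' end and not at the most upstream. Both insulin genes, Ins1 and Ins2, were listed at 0.

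Markers of non-neuronal cells that midbrain tissue can hold were not called in breadth. CpG-matched random medians were 1.56 kb for the oligodendrocyte list, 1.36 kb for astrocytes, 1.92 kb for endothelium, 1.64 kb for mural cells and meninges, and 1.04 kb for choroid plexus. For microglia and blood they were 0.0488 kb and 0.293 kb, which left little room for a low call, and unmatched their percentiles were 5.71 and 4.6. In the oligodendrocyte lineage 7 of 11 genes were marked, with a median of 1.41 kb ± 0.00141. Olig2, a factor of oligodendrocyte precursors, had 6.05 kb ± 0.0891 and Pdgfra 4.35 kb ± 0.105, while Sox10, marked in 1 library, had 0.244 kb ± 0.00495 and the myelin gene Plp1 was listed at 0. Astrocyte genes had 0.961 kb ± 0.0219 with 5 of 9 marked. The glutamate transporter gene Slc1a2 had 6.94 kb ± 0.202 and Fgfr3 5.56 kb ± 0.447, and S100b and Aldh1l1 were listed at 0, the latter with 1.98 kb ± 0.702 at its principal 5' end. Microglial genes were marked at 2 of 12 promoters with a median of 0.429 kb ± 0.0499, with Hexb at 2.42 kb ± 0.168, Spi1, with no promoter peak, at 1.649 kb and 1.654 kb in the 2 libraries (0.247 kb and 0.284 kb at its principal 5' end), and both Csf1r and Cx3cr1 at 0. Endothelial genes were marked at 7 of 12 with a median of 1.75 kb ± 0.00707, with Sox18 at 4.44 kb ± 0.151, Esam at 2.36 kb ± 0.0332 and both Emcn and Pecam1 at 0, the latter with 0 kb and 0.695 kb in replicates 1 and 2 at its principal 5' end.

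Mural and meningeal genes were marked at 9 of 12 promoters with a median of 2.58 kb ± 0.154. The forkhead gene Foxc1 had 5.92 kb ± 0.332 and Prrx1 4.55 kb ± 0.303, whereas Rgs5, marked in 1 library, had 0.134 kb ± 0.189 and Lum was listed at 0. Choroid plexus and ependymal genes were marked at 2 of 8 with a median of 0.290 kb ± 0.00707, with Foxj1, a factor of motile cilia, at 4.56 kb ± 0.0453, Kcne2, with no promoter peak, at 2.11 kb ± 0.00566 and both Aqp1 and Folr1 at 0. Blood genes were marked at 4 of 12 with a median of 0.264 kb ± 0.0173, with Klf1 at 4.96 kb ± 0.179, Epor at 3.75 kb ± 0.429 and both Alas2 and Cd19 at 0. Of the negative control families, 2 of 1134 olfactory receptor genes, 1 of 330 vomeronasal receptor genes and 1 of 57 keratin-associated protein genes were marked, each family with a median of 0 kb. Their CpG-matched random medians were 0 kb too, at percentiles near 50, so the matched comparison could not call these families low. Unmatched, the percentile was 0 for both receptor families and 0.01 for keratin-associated proteins.

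Of the 29 lists, patterning and neural progenitor genes had the highest median numbers of distal H3K4me2 regions. Midbrain and isthmus patterning genes had a median of 5.5 ± 0.707 distal regions within 100 kb of the 5' end, against 1.5 for random lists, with Pax2 at 14 and 10 in replicates 1 and 2 and Lmx1b at 11.0 ± 1.41. Neural progenitor genes had 4.5 ± 0.707, with Hes5, an effector of Notch signalling, at 9.0. Glutamatergic genes had 3.25 ± 0.707, axon guidance genes 3.0, heart genes 2.75 ± 0.354 and oligodendrocyte lineage genes 3.5 ± 0.707, which also placed them in the highest 2.5% in both libraries. Ebf3 had 9.5 ± 2.12 distal regions, Efna5 9.5 ± 0.707 and Olig2 9.0 ± 1.41. Of these 6 lists, only patterning and neural progenitor genes kept this place under every alternative run. Forebrain transcription factors had 3.5 ± 0.707, at percentiles of 96.97 and 99.98 in replicates 1 and 2, and hindbrain and cerebellum genes 3.75 ± 0.707, at 99.3 and 95.6. Other epithelia had 2.5 ± 0.707, at 93.6 and 99.8. These 3 lists therefore stood apart in a single library. Matched on gene length, the forebrain and hindbrain lists stood apart in both, at 99.9 and 99.8. Hox genes had 2.0 distal regions and did not stand apart.

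The 25 protein-coding entries with the widest H3K4me2 spanned breadths from 20.0 kb at Meis2 to 15.7 kb. Behind Meis2 came the POU genes Pou3f2 (chromosome 4, 22482780 to 22488366) at 19.8 kb ± 0.0106 and Pou3f3 at 19.8 kb ± 0.0127, the nuclear receptor gene Nr2f1 at 19.6 kb ± 0.00141, and Skida1 with its neighbour Mllt10 at 19.1 kb ± 0.247. Zic4 with Zic1, 4930412O13Rik (with 9230102O04Rik and Gata3 close by) at 19.1 kb ± 0.177, Lhx1, Ebf3 and Bahcc1 at 18.9 kb ± 0.154 followed, then Lhx5, Sox2, En2, Barhl2 and Setd1b with Rhof. Zfhx4 had 17.3 kb ± 0.544, the Iroquois genes Irx2 and Irx5 17.1 kb ± 0.148 and 16.9 kb ± 0.320, Pax3 came next, and Zic2 with Zic5 had 16.8 kb ± 0.0962. The last places went to Asic4, which encodes a member of the acid-sensing channel family, at 16.7 kb ± 0.0820, Otx1, En1, A930004D18Rik at 15.7 kb ± 0.344 and Nr2f2 at 15.7 kb ± 0.144. Breadth cannot exceed the window of 20.0 kb, so the order among the widest genes is compressed.

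Joined regions extended well beyond single promoters at some of these loci. Of 29823 replicated regions 199 were 10 kb or wider, and 158 of those held the 5' end of a protein-coding gene. The widest, 38.8 kb on chromosome 9 from 91349155 to 91387954, held the 5' ends of Zic1 and Zic4, and peaks covered 34.3 kb ± 0.542 of it in the libraries. A region of 33.2 kb on chromosome 13 from 83713132 to 83746378 held the microRNA gene Mir9-2 and the long non-coding RNA gene C130071C03Rik, with the nearest protein-coding 5' end, that of Mef2c, 209098 bp away. On chromosome 8 a region of 32.3 kb from 108694960 to 108727272 lay inside Zfhx3, 752316 bp from the gene's most upstream annotated 5' end. By class 94.4% of it was intronic. Distances and classes used only the most upstream 5' end of each gene, so other transcript 5' ends of Zfhx3 were not considered. Regions at Pou3f3 (32.0 kb, chromosome 1, 42683037 to 42715080), Nr2f2 (30.1 kb, chromosome 7, 70342722 to 70372776) and Ebf3 (28.8 kb, chromosome 7, 137294636 to 137323423) came next. Meis2 (27.7 kb, chromosome 2, 116049040 to 116076692) and the Gata3 locus (25.3 kb, chromosome 2, 9865140 to 9890468) followed. The last 2 of the 10 widest were a region of 25.3 kb on chromosome 3 from 88198224 to 88223474, which held Mir9-1 and no protein-coding 5' end, and one of 24.3 kb at Nr2f1 on chromosome 13 from 78187032 to 78211368. With peaks joined only where they overlapped, 91 regions reached 10 kb, and with joining within 3 kb 359 did. Of the 10 widest regions, 4 were overlapped by the 10 widest under joining at overlap alone.

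Peaks with the highest fold enrichment in the replicated list were a different set. Egr1, an immediate early transcription factor gene, led at 82.2-fold, with a peak of 4.43 kb on chromosome 18 from 34859019 to 34863446 whose summit lay in an untranslated exon sequence 1555 bp from the 5' end. Rreb1 had 77.2-fold (chromosome 13, 37777748 to 37779807), Nr3c2, the mineralocorticoid receptor gene, 75.1-fold (chromosome 8, 76898512 to 76903201) and Col27a1 73.2-fold (chromosome 4, 63213623 to 63216742). A peak of 8.80 kb on chromosome 3 from 17783536 to 17792336 had 72.6-fold and held the 5' end of the microRNA host gene Mir124-2hg, 161742 bp from the nearest protein-coding 5' end, that of Cypt12. Usp43 and the cell cycle gene E2f2 had 71.6-fold each, Tbc1d1 70.9-fold with the summit in an untranslated exon 3402 bp from the 5' end, and Adgrg6 and E2f8 70.7-fold each. These distances are to the most upstream annotated 5' end of a gene, and other transcript 5' ends, such as those of Egr1 and Tbc1d1, were not considered. In the separate libraries the Egr1 peak had 71.5-fold and 67.7-fold.

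The 5 genes with the largest difference in breadth between the libraries differed by at least 1.82 kb. The median absolute difference in breadth over genes marked in both libraries was 177 bp. Nkx2-1, a factor of the ventral forebrain, differed most, with 4.43 kb in replicate 1 and 1.96 kb in replicate 2 and a peak at its most upstream 5' end in replicate 1 alone, while another transcript 5' end was marked in both. Foxb1 had 16.2 kb and 14.2 kb, Lbx1 3.83 kb and 1.99 kb, and the glycine transporter gene Slc6a5 3.83 kb and 2.01 kb. The netrin receptor gene Unc5a was wider in replicate 2, at 5.96 kb and 7.83 kb. With 1 library per pool these differences have no replicate check.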

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

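Tests on peaks of a single library were chosen only after the result was seen. The tests on the gene lists and the Hox genes were written before their own results were seen, although the Hox percentile matched on gene length alone was already known.

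Signal appeared in data that the comparisons left out. The replicated list held 14 peaks on scaffolds outside the assembled chromosomes, of which 6 lay on a scaffold assigned to the X chromosome. Replicates 1 and 2 had 16 such peaks each.

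Wide H3K4me2 at 9 gene lists may reflect properties of the promoters other than the lists' membership. With random lists matched on promoter fold enrichment in place of CpG content, 9 of the 9 lists stayed in the highest 2.5% in both libraries. That argues against stronger enrichment at these promoters as the whole cause. With matching on the number of annotated gene 5' ends within 10 kb, also in place of CpG content, again 9 of 9 stayed. That argues against the number of neighbouring 5' ends in the window as the whole cause. CpG content was not held in either test, so random lists could differ from these lists in it. Midbrain and isthmus patterning genes had a median promoter fold enrichment of 19.9, below the 33.9 of housekeeping genes, and a breadth of 13.0 kb against 4.30 kb. No biological explanation was tested, since the design has 1 group, and expression of these genes was not analysed here.

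Narrow H3K4me2 at Hox genes was weighed against gene length and against a single cluster counted many times. With random lists matched on CpG content and gene length together, the Hox percentile was 0 in both libraries, which argues against short genes as the whole cause, while matching on length without CpG content gave 29.2. Tested alone with matching on CpG content only, 4 of 4 clusters were in the lowest 2.5% in both libraries. Medians were 1.097 kb (Hoxa), 0.562 kb (Hoxb), 0.372 kb (Hoxc) and 1.88 kb (Hoxd). Hoxd was close to the limit, at percentiles of 1.78 and 2.42 in replicates 1 and 2. Under that matching this argues against a single cluster as the source. Single clusters were not tested with gene length matched, and genes of a cluster share windows. Whether reads shared between paralogs matter was not tested. No biological explanation was tested.

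Peaks of 1 library without a partner in the other, 9357 in replicate 1 and 5573 in replicate 2, may be weak peaks near the calling threshold. In the upper part of each library's peaks by fold enrichment at most 0.0174% lacked a partner (4 of 22990 in replicate 1 and 0 of 21675 in replicate 2), against 40.7% and 25.7% in the lower part. These shares restate those by fold enrichment already seen, so they exclude nothing and the explanation stays open. A difference in input files, of which the list of replicate 1 had 1 more, cannot be told apart from the library, since each library has its own set. Differences between the pools of embryos stay open and were not tested.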

How the results depend on the processing

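The principal transcript 5' end was chosen as an alternative after seeing the data, and all others were planned. No result reversed. The 9 lists with wide H3K4me2 kept that place under every alternative run, and the germ cell list stayed low. The Hox list lost its place only when matched on gene length (percentile 29.2). Of the 6 lists with many distal regions, patterning and neural progenitor genes kept their place under every alternative. The cause of these changes was not tested. Depth is unknown, which limits what a missing peak can mean.

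At a −log10 q of at least 5, which removed weak peaks by construction, replicate 1 had 30607 peaks and replicate 2 had 30600. Shared peaks were then 90.6% and 92.8%, and regions were 50.5% promoter, 12.3% exon, 16.2% intron and 21.04% intergenic. Overlap of at least 50% of the peak gave 72.5% and 81.7% shared peaks, and of both peaks 66.5% and 70.6%, a stricter demand by construction. With promoters within 2 kb, regions were 49.3% promoter, 11.2% exon and 21.5% intergenic. The pooled list gave 42.1% promoter, 11.8% exon, 22.0% intron and 24.1% intergenic. Single libraries (leaving out either replicate) gave 43.3% to 45.6% promoter, 11.8% to 11.9% exon, 20.0% to 21.8% intron and 22.5% to 23.2% intergenic. Regions of 10 kb or more numbered 91 with peaks joined only where they overlapped and 359 with joining within 3 kb. Lists low in breadth numbered 6 with unmatched random lists. Lists low in distal regions numbered 2 matched on gene length, 3 matched on the number of 5' ends within 100 kb and 3 unmatched. Among calls of single lists and the named regions, 563 were labelled unchanged, 37 passed a threshold they had not passed, 14 no longer passed it and 1 moved. A list not apart in both settings counted as unchanged whatever its percentile. Dopaminergic genes, for example, went from 98.2 to 45.8 at a −log10 q of at least 5.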

Other observations

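The values in this part were chosen after the data were seen. The 3 genes of miR-9, a microRNA of neural progenitors, lay in wide H3K4me2. Among 2202 annotated microRNA genes, Mir9-3 ranked 1, with 19.0 kb ± 0.0537 (SD, n = 2) covered within 10 kb of its 5' end, Mir9-1 ranked 3 with 17.7 kb ± 0.371, and Mir9-2 ranked 5 with 16.5 kb ± 0.0672. The genes of miR-124, a microRNA of neurons, had 16.5 kb ± 0.499 at Mir124a-2, 14.01 kb ± 0.187 at Mir124a-1 and 9.86 kb ± 0.369 at Mir124a-3. The median over all microRNA genes was 0 kb, and 26 had 10 kb or more. Mir3093 and Gm25641, at ranks 2 and 4, lie within 10 kb of Mir9-1 on chromosome 3 and share its peaks.

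Grouped by the stem of the gene symbol, 937 families had 4 or more protein-coding members. The 5 Zic genes had a median breadth of 16.8 kb ± 0.0962, the 4 Pou3f genes 15.8 kb ± 0.176, the 4 Ebf genes 12.4 kb ± 0.218 and the 6 Irx genes 11.5 kb ± 0.0764. Groucho corepressor genes (Tle, 5 members) had 9.11 kb ± 0.133, and the 19 Sox genes 7.66 kb ± 0.0820 with 18 marked. Ribosomal protein genes had 3.24 kb ± 0.0923 (Rpl, 54 members) and 2.96 kb ± 0.0103 (Rps, 44 members). Of 22 Pcdhb genes, a clustered protocadherin family, 1 was marked and the median was 0 kb. Neighbouring members share windows, so these medians rest on fewer loci than genes. Each median is over members' means of both libraries and can lie outside both library medians, as for Rps genes.

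Of the replicated peaks on assembled chromosomes, 33237 overlapped a peak in both libraries, 1919 overlapped one in replicate 1 only, 964 in replicate 2 only and 192 in neither. Those in neither had a median fold enrichment of 2.86, against 15.6 for those in both. On the Y chromosome 4 genes were marked in both libraries, Kdm5d, Uty, Ddx3y and Eif2s3y, the last with 0.695 kb in replicate 1 and 0.604 kb in replicate 2.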
